A study of Mus musculus with 2 samples.

How the data were processed

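CTCF ChIP-seq was done on heart of B6NCrl mice at postnatal day 0, in 2 libraries of 1 group. Replicate numbers are those of the labels, which also give both libraries 1 tissue sample and 1 donor identifier.

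The deposited values are 5 peak lists in narrowPeak format on mm10, per the labels and the text files beside them. The 3 relaxed lists hold 300000 peaks each. According to those text files, they were called by the authors on the alignments of replicate 1, of replicate 2 and of both together, each against a control alignment that is not used here. The optimal and conservative lists were derived by the authors from these by IDR. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak is the deposited one, always above 0. It is used to rank and describe peaks within a list, since pooled values are about the sum of those of the replicates. Signals of the 2 libraries were also set side by side without scaling, so SDs of signal between them include any difference in scale. The q-value score in the deposited lists falls below 0 in 3 lists and levels off at the top, so it was used only to describe them: 98.1% of optimal peaks and 17.0% of pooled relaxed peaks have a score above that of q = 0.05. The deposited peak score of the IDR lists was not used. Summits are the peak start plus the offset in bp given by the authors. Relaxed lists cut at a fixed number of peaks include background: at equal length of list, weak peaks near the end are less certain than strong ones. Read depth is not given in the peak lists, so no counting interval on a signal is given.

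The mouse genome GRCm38 (mm10), with repeats masked in lower case, and GENCODE M21 gave sequence and annotation. Analyses of position used the assembled chromosomes 1 to 19, X and Y, which hold 44518 of the 44533 optimal peaks. Gene 5' ends are the ends of the gene records of all types. A summit within 1000 bp of one was called promoter, then coding exon, other exon, intron or intergenic, in that order and over all genes. Random positions were drawn on known bases with the same number per chromosome as the optimal list, 100 times. The core consensus CCASYAGRKGGCRS, of 14 bases, was searched on both strands with at most 2 mismatches within 50 bp of each summit and in windows of that size 1000 bp to either side. These were compared by an exact McNemar test over peaks, which are not replicates. A core was called masked when at least 7 of its bases were in lower case. For orientation, neighbouring peaks with exactly 1 best core and a gap of 5 to 200 kb were compared with 10000 shuffles of the strands within each chromosome. Convergent means a plus strand core followed by a minus strand core.

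Replicates were compared by the share of the N strongest peaks of replicate 1 with a summit within 100 bp of one of the N strongest of replicate 2, where N is the number of optimal peaks, and after a shift of 1 Mb. The replicates' own N strongest peaks also gave the mean and SD over the 2 libraries for shares, and the values with either library left out. Lists of genes (17, covering sarcomere, transcription factor, channel, metabolic and fetal genes of the heart, other cell types, Hox, imprinted, architectural, X inactivation, cell cycle and housekeeping genes) were fixed before the data were examined. For each, the share with a peak within 10 kb of the 5' end was compared with that of all other protein-coding genes on chromosomes 1 to 19 and X by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Of the listed names, 3 matched no gene record. Some list members, such as H19 and Xist, encode no protein, while the genes they were compared with all do. Genes are not independent, as neighbours share peaks. Intervals on shares are exact binomial at 95% and cover counting error only.

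Genes named in the text follow a rule also fixed before the data were examined: the protein-coding genes whose 5' ends are nearest to the 15 strongest optimal peaks, the 2 members of each list with the strongest peak within 10 kb, and 12 genes named in advance. Of the genes this rule takes, 2 are not reported here. Other genes named, such as list members without a peak and genes around the named loci, were chosen after their values were seen. Alternatives fixed in advance were the conservative list, each replicate left out, other windows, mismatch limits, gaps, overlaps and list lengths, other 5' ends, matched backgrounds (10000 draws) and clustered genes counted once. Narrow gap classes were added after the data were seen.

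Replicate overlap, the core search, the signal difference by core, the orientation test and the gene list test were tested on simulated data with known answers. The promoter share, the rank correlation, the promoter signal difference and the X ratio were not. All planted cores were found with 0 mismatches (100%), 2.16% of 2499 random windows had a core by chance, and a planted log2 difference of 1 came back as 1.02. Of every other neighbouring pair, about 20% were turned to face each other, and 20 of 20 such simulated sets were called. With random strands 1 of 20 was called. A deficit of convergent pairs was not simulated. For lists of 40 genes, a share of 75% against 50% was called at an unadjusted p under 0.05 in 88.4% of simulations and an equal share in 3.6%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. The 15 optimal peaks on other sequences were left out of analyses of position.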

Results

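CTCF, the zinc finger protein that holds chromatin loops and insulates enhancers from promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole heart of newborn mice of the B6NCrl strain, at postnatal day 0. The 2 libraries form 1 group, CTCF ChIP in heart, and are called replicate 1 and replicate 2. The labels give both libraries the same tissue sample and donor, so the spread between them may be technical. The sex of the animals was not collected. Each library gave a relaxed list of 300000 peaks, as did both together, and 2 lists passed the authors' irreproducible discovery rate (IDR) filter. With 1 group there is no contrast between conditions. The comparisons made here ask how well the 2 libraries repeat each other, where CTCF sits in the genome, which sequence lies beneath it and near which genes it is found. Read depth per library is not given in the peak lists, so counting error on a peak's signal is unknown.

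The heart genome carried 44533 CTCF peaks in the optimal IDR list and 43221 in the conservative one. The strongest site lay on chromosome 7 between genes, 40.82 kb downstream of the 5' end of Glrx3, which encodes a glutaredoxin. Its pooled signal value was 425, against a list median of 60.8, and the libraries gave 214 ± 9.19 (SD, n = 2). The next strongest lay 19.12 kb upstream of Fnbp1l (417) and in an intron of Fam129b (408). Among the 15 strongest sites were further ones within Col18a1, which encodes a basement membrane collagen (signal 401), within Pink1, a mitochondrial quality control kinase (396), in a coding exon of Gdf15, a stress-induced cytokine (395), and 9.31 kb upstream of the cation channel gene Trpv4 (396). By distance to the 5' end, the protein-coding genes nearest to the others of these 15 sites were Slc41a3, Gbx1, Slc16a8, Rbm19, Snx19, Gm16253, Lbr and Ptges2, at signals of 384 to 404. The Slc41a3 site lay 132.88 kb from that gene's 5' end, in an intron of Iqsec1, and the Slc16a8 site lay 11.38 kb from its 5' end, in an intron of Pick1. All 15 sites carried a CTCF core with at most 2 mismatches. The core at Glrx3 read GCACCAGGGGGCGC (chromosome 7, 137478473 to 137478486, plus strand, 1 mismatch). That at Rbm19, 13.52 kb upstream of the gene, read CCACCAGGGGGCGC (chromosome 5, 120102930 to 120102943, minus strand, 0 mismatches), and that within Pink1 read CCACTAGGTGGCGC (chromosome 4, 138319718 to 138319731, plus strand, 0 mismatches). All positions are in mm10.

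The optimal list covered 8.94 Mb with a median peak width of 224 bp. The IDR lists were not nested: 39803 summits were in both, 4730 were in the optimal list alone and 3418 in the conservative list alone. Peaks in both lists had a median signal of 72.4, against 16.1 for those in the optimal list alone and 16.0 for those in the conservative list alone.

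The libraries found largely the same sites. Of the 44533 strongest peaks of replicate 1, 85.3% (95% exact binomial interval 85.0 to 85.7%) had a summit within 100 bp of one among the 44533 strongest of replicate 2, where a shift of 1 Mb gave 0.472%. Among the 15 strongest sites the SD between the libraries ran from 1.82 near Trpv4 to 30.2 in Col18a1, on means of 193 to 214 (n = 2). These SDs are of unscaled signals and do not rank how well a site repeated. Replicate 2 was lower in general, with a median log2 ratio to replicate 1 of -0.18 in the strongest signal decile. At the stronger of 2 weak sites near the 5' end of Ctcf itself the libraries gave 6.46 and 17.1. At the Gata4 intron site they gave 13.7 and 6.13. Across the 43232 optimal peaks seen in both relaxed lists, signals had a Spearman correlation of 0.947. It is described across peaks, which are not independent replicates. These peaks had passed the authors' IDR filter and were required in both lists, which may raise the correlation. The log2 ratio of replicate 2 to replicate 1 had a median of -0.22. Its SD was 0.78 in the weakest signal decile and 0.16 in the strongest. Its absolute value had a median of 1.05 for peaks in the optimal list alone and 0.27 for those in the conservative list alone. Of these peaks, 78.3% and 89.7% were found in both replicates. The overlap depended on how many peaks were compared, at 88.8% for the top 10000 and 48.6% for the top 100000.

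CTCF peaks were found at promoters more often than random positions were. Summits within 1000 bp of a gene 5' end made up 14.1% of the optimal list (95% exact binomial interval 13.8 to 14.5%), against 3.97% of random positions, an excess of 3.57-fold that none of 100 random draws reached. The replicates' own strongest peaks gave 14.2% ± 0.295 (SD, n = 2). Promoter sites included Rplp0, a ribosomal protein gene (summit 157 bp upstream, signal 258), Slc2a4, which encodes the insulin-responsive glucose transporter (897 bp upstream, signal 219), Gfap, an astrocyte filament gene (87 bp upstream, signal 229.7), and H13, which hosts an imprinted locus (57 bp upstream, signal 278). Coding exons held 2.38% of summits against 1.32% at random, other exons 4.77% against 2.79%, and introns 43.7% against 41.8%. Intergenic sequence held 35.0%, less than the 50.1% at random, and fewer than in any of the 100 draws. Promoter peaks were weaker than the rest, with a median signal of 47.0 against 63.4. This log2 difference of -0.43 was, by the replicates' own signals at the optimal peaks found in both, -0.37 in replicate 1 and -0.30 in replicate 2, and no test was made on 2 libraries.

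**Figure D1:**
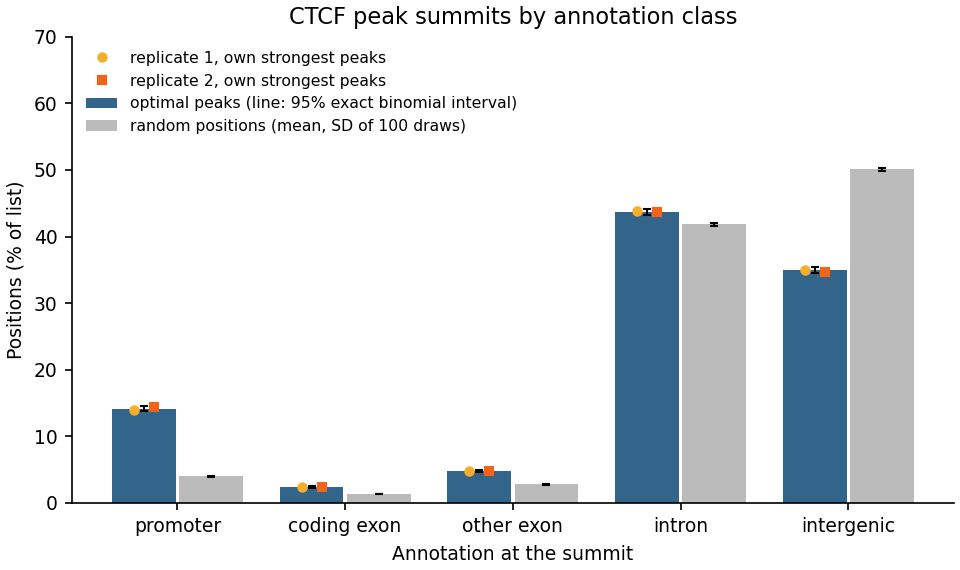
Share of optimal CTCF peak summits (blue bars, with 95% exact binomial intervals) and of random positions (grey bars, mean and SD of 100 draws) in each annotation class, in percent of the list, with points for the 2 replicates' own strongest peaks. Promoters hold 14.1% of summits against 3.97% at random, and intergenic sequence 35.0% against 50.1%.

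The CTCF core consensus CCASYAGRKGGCRS lay within 50 bp of most summits. With at most 2 mismatches it was found at 73.5% of optimal peaks (95% exact binomial interval 73.1 to 73.9%), against 2.79% and 2.94% of windows 1000 bp to the left and right. The summit alone had a core at 31785 peaks and the left window alone at 302 (exact McNemar test, two-sided, log10 p = -8918). The replicates' own strongest peaks gave 72.3% ± 1.56 (SD, n = 2). With at most 3 mismatches the share was 91.3%, against 17.3% and 17.1% in the left and right windows. With at most 1 mismatch it was 42.4%, against 0.382% and 0.389%. Sites with 0 mismatches included those near Gfap (CCACTAGATGGCAG, chromosome 11, 102900988 to 102901001, plus strand), near Ccnd2, which encodes cyclin D2 (CCACTAGGTGGCAG, chromosome 6, 127147870 to 127147883, plus strand, in an exon), near Nppa, the atrial natriuretic peptide gene (CCAGCAGGGGGCAC, chromosome 4, 148008577 to 148008590, minus strand, in an intron of Clcn6), and at Xist (CCAGCAGGTGGCAG, chromosome X, 103484232 to 103484245, plus strand). Peaks with a core were stronger than peaks without one, with median signals of 78.7 and 31.3. This log2 difference of 1.33 was, by the replicates' own signals at the optimal peaks found in both, 1.27 in replicate 1 and 1.24 in replicate 2. The share with a core was 43.5% in the weakest signal decile and 91.8% in the strongest. Core-bearing shares differed by place as well, at 54.7% of promoter peaks, 75.5% of intron peaks and 79.2% of intergenic peaks.

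**Figure D2:**
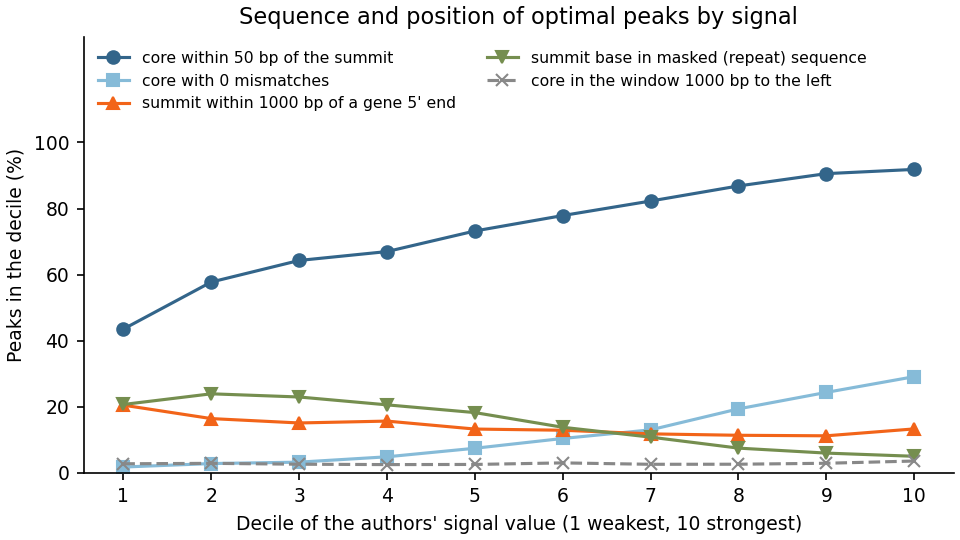
Percent of optimal peaks with a core within 50 bp of the summit, with a core of 0 mismatches, with a summit within 1000 bp of a gene 5' end, and with a summit in masked sequence, by decile of the authors' signal value (1 weakest, 10 strongest), with a dashed line for the share with a core in the window 1000 bp to the left. The core share goes from 43.5% to 91.8%, and the masked share from 20.7% to 5.01%.

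Neighbouring core-bearing peaks faced each other slightly less often than shuffled strands gave at gaps of 5 to 200 kb, and the direction of this difference depended on the gap. Over that range 5970 of 24411 pairs (24.5%) were convergent, against 25% ± 0.192 (SD of 10000 shuffles within chromosomes; two-sided permutation p = 0.0056). At gaps of 50 to 500 kb the convergent share was 31.2% of 10838 pairs, against 25% shuffled (permutation p = 0.0002, the smallest these shuffles can give). Among peaks at or above the median signal it was 24.7% at 5 to 200 kb, not past the threshold (permutation p = 0.281), a range that pools opposite differences: in these peaks it was 18.4% at 5 to 50 kb and 33.8% at 50 to 500 kb. In gap classes chosen after the data were seen, the convergent share was 18.4% at 5 to 10 kb, 19.9% at 10 to 25 kb, 24.3% at 25 to 50 kb, 28.7% at 50 to 100 kb, 31.9% at 100 to 200 kb and 37.2% at 200 to 500 kb. The divergent share went the other way, from 29.0% in the shortest class to 16.1% in the longest. In all of these classes except 25 to 50 kb (permutation p = 0.211) the convergent share differed from the shuffled one at the smallest p the shuffles can give.

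**Figure D3:**
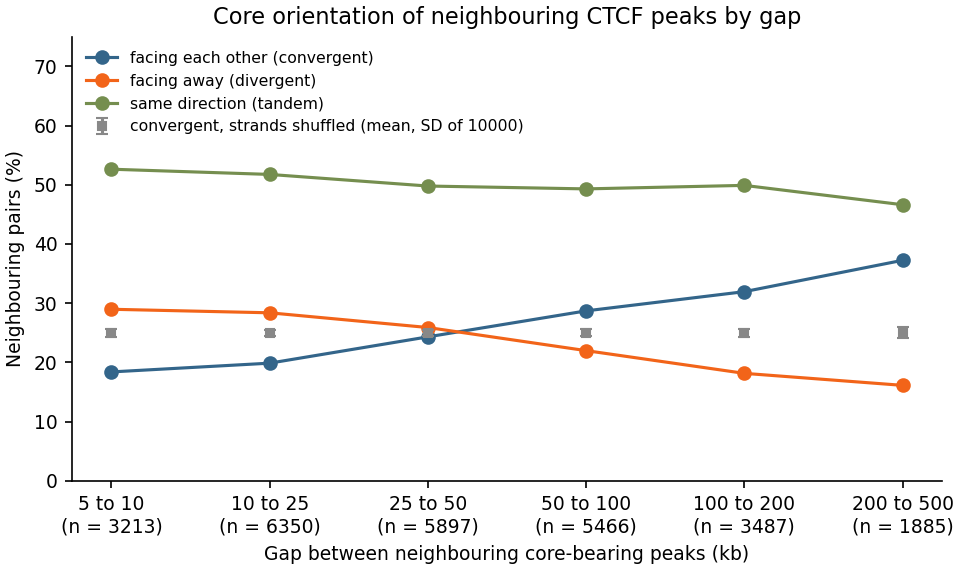
Percent of neighbouring core-bearing optimal peaks that face each other, face away or point the same way, by the gap between them in kb (n, pairs per class), with grey squares for the convergent share with strands shuffled (mean and SD of 10000 shuffles). The convergent share is 18.4% at 5 to 10 kb and 37.2% at 200 to 500 kb.

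A larger share of Hox and imprinted genes than of protein-coding genes outside each list had a CTCF peak within 10 kb. The imprinted list also holds genes that encode no protein, such as H19. The difference did not pass the test when members close to each other were counted once. Within 10 kb of the 5' end, 30 of 39 Hox genes (76.9%) and 41 of 57 imprinted genes (71.9%) had a peak, against 50.7% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 0.0113 for both, Benjamini-Hochberg over 17 lists). Both replicates' own strongest peaks gave the same 76.9% and 71.9%. The strongest peaks near Hox genes were in an intron of Hoxc5 3.01 kb upstream of Hoxc8 (signal 201.4) and at the Hoxa7 promoter, within 8.48 kb of Hoxa3 (187). Among imprinted genes they were at H13 (278) and at Mcts2 (9.92 kb from its 5' end, signal 227), which lies within H13. With members within 10 kb of each other counted once, the shares were 70% of 20 Hox genes and 70.4% of 54 imprinted genes, and neither list passed (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.219 and 0.0616). Neither passed with a 5 kb window (51.3% and 56.1%, exact test, adjusted p = 0.215 and 0.0755), and imprinted genes also did not with the conservative list (64.9%, adjusted p = 0.0829) or a 50 kb window (91.2%, adjusted p = 0.159). Hox genes did pass in these 2 settings (76.9% and 100%, exact test, adjusted p = 0.011 and 0.0173). Against genes matched on neighbouring 5' ends both lists passed (56.2% and 47.2% expected, permutation adjusted p = 0.0442 and 0.0068).

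Of the heart lists, none passed the test over 17 lists with the optimal peaks at 10 kb against all other genes, although some did with other settings or with 1 library alone. Cardiac transcription factors had a peak at 25 of 34 genes (73.5%, adjusted p = 0.0523), ion channel and calcium handling genes at 23 of 32 (71.9%, adjusted p = 0.0693), fatty acid and mitochondrial genes at 23 of 32 (71.9%, adjusted p = 0.0693), sarcomere genes at 20 of 30 (66.7%, adjusted p = 0.188) and fetal program genes at 11 of 18 (61.1%, adjusted p = 0.584; Fisher's exact test, two-sided, Benjamini-Hochberg). With each replicate's own strongest peaks the cardiac transcription factors did pass, at 82.4% in replicate 1 and 76.5% in replicate 2 (Fisher's exact test, adjusted p = 0.00345 and 0.0177), and against genes matched on neighbouring 5' ends (46.5% expected, permutation adjusted p = 0.0221). They did not pass in the conservative list (67.6%), at 5 kb, at 50 kb or with clustered members counted once (exact test, adjusted p = 0.0985, 0.0949, 0.159 and 0.0616). Ion channel genes passed in replicate 1 (75%, exact test, adjusted p = 0.0304), in the conservative list (78.1%, adjusted p = 0.011), at 5 kb (65.6%, adjusted p = 0.049) and against matched genes (permutation adjusted p = 0.0442). They did not pass in replicate 2 (68.8%), at 50 kb or counted once (exact test, adjusted p = 0.0973, 0.159 and 0.0866). Without replicate 1, in the peaks of replicate 2, sarcomere genes (73.3%, exact test, adjusted p = 0.0474), fatty acid genes (75%, adjusted p = 0.0312) and cell cycle genes (74.2%, adjusted p = 0.0379) passed too. The strongest sarcomere site lay 2.91 kb upstream of Mybpc3, which encodes cardiac myosin binding protein C, in a coding exon of the adjacent gene Spi1 (signal 373). Tnnc1, the troponin C gene, had one 7.34 kb downstream of its 5' end in an intron of Nisch (231). Among calcium genes, Jph2, a junctional membrane protein gene, had a site 3.43 kb upstream (313). The strongest sites among transcription factors were near Foxc2 (295) and Tbx2 (225), among metabolic genes near Slc2a4 (219) and the fatty acid transporter gene Slc27a1 (216), and in the fetal program near Ankrd2 (246) and Tnni1, the slow skeletal troponin I gene (202). Actc1, Myl7, Hand1, Mef2c, Tbx5, Hcn4, Gja5 and Pdk4 had no optimal peak within 10 kb.

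Lists of other cell types and of general functions did not pass the test with the optimal peaks at 10 kb. Peaks were within 10 kb of 19 of 28 endothelial genes, led by Nos3 (signal 299) and Sox18 (264), 17 of 28 fibroblast genes, led by Mmp2 (343) and Col1a1 (223), and 10 of 17 smooth muscle list genes, led by Casq1 (255), better known from skeletal muscle, and Mcam (193). Neural genes had a peak at 18 of 26 (Nes 235, Gfap 229.7), blood genes at 11 of 27 (Cx3cr1 187, Cd68 139) and hepatic genes at 7 of 21 (Apob 208). Hepatic genes had the lowest share, 33.3% (95% exact binomial interval 14.6 to 56.97%; adjusted p = 0.219), and Alb, Afp, Ttr and Cyp7a1 were among those with none. Cell cycle genes had a peak at 19 of 31 (Ccnd2 314, E2f2 266), architectural genes, such as cohesin subunits, at 18 of 34 (Esco1 229.6, Pds5b 193), and housekeeping genes at 21 of 31 (Rplp0 258, Rpl13a 214). Of the X inactivation list, which also holds X-linked genes far from Xist such as Firre and Kdm5c, 9 of 15 genes had one, with the same site leading for Xist and Jpx (142). At 50 kb, where most genes have a peak, blood genes turned from below the other genes to above them (100%, against 82.6%; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.04), and cell cycle and housekeeping genes also passed (100% each, adjusted p = 0.0219).

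**Figure D4:**
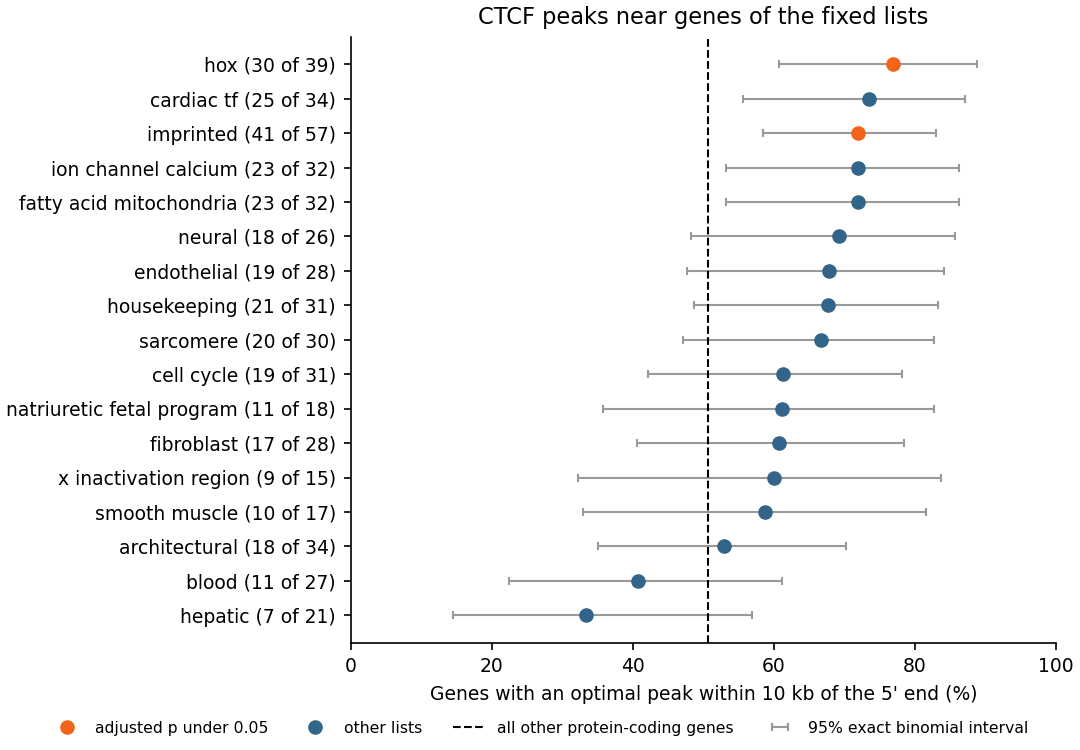
Percent of each list's genes with an optimal peak within 10 kb of the 5' end, with 95% exact binomial intervals and the counts beside each list name, and a dashed line at the share of other protein-coding genes, 50.7%. The Hox (76.9%) and imprinted (71.9%) lists have an adjusted p under 0.05, but not with members within 10 kb of each other counted once.

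At the H19 and Igf2 locus, where CTCF is known to bind the imprinting control region, 14 optimal peaks lay in 208 kb of chromosome 7, which is 3.33 times the density of the chromosome. Of these, 4 lay 1.12 to 3.64 kb upstream of H19, at summits 142579265, 142580325, 142580775 and 142581780, all intergenic. The strongest of them, at 142580775, had a pooled signal of 87.9 and 44.1 ± 5.58 (SD, n = 2) in the libraries. The other 3 had signals of 25.2, 75.4 and 52.2, and only the weakest, at 142579265, had a core with at most 2 mismatches. The best match had 3 mismatches at 142580325 and at 142580775, and 4 at 142581780. Igf2, a fetal growth factor gene, had its strongest peak 5.52 kb upstream (summit 142672331, signal 143), with the core CCACCAGATGTCAA (chromosome 7, 142672324 to 142672337, minus strand).

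The Hoxa cluster held 8 peaks in 145 kb, 3.20 times the density of its chromosome, with cores on the minus strand at 4 sites (at Hoxa5, at Hoxa7, at Hoxa10 and 5714 bp from the 5' end of Hoxa4) and on the plus strand at 1, between Hoxa11 and Hoxa13. The Hoxb, Hoxc and Hoxd clusters held 9, 5 and 7 peaks, at 1.53, 1.75 and 2.72 times the density of their chromosomes. Around Myh6 and Myh7, the genes of the cardiac myosin heavy chains, there were 13 peaks in 153 kb, 5.85 times the density of the chromosome. This window reached further beyond its genes than those of the other loci, so the densities cannot be ranked against each other. The peaks near the 5' ends of Myh6 and Myh7 were weak, with signals of 17.9 at 1.49 kb upstream of Myh6 and 14.5 at 288 bp within Myh7. Neither had a core. Stronger ones lay outside the pair, with signals of 162 at summit 54900589, 151 at summit 54939563 and 196 at summit 55015153, the last at the Ngdn promoter. Tnnt2, the cardiac troponin T gene, had its strongest peak 7.24 kb upstream (142), Nppa one 7.86 kb from its 5' end (174) and Actb, cytoplasmic actin, one at 960 bp within the gene (149.6). Weak peaks lay at the cohesin gene Rad21 (139 bp upstream, signal 30.3), at Ctcf (816 bp from its 5' end, signal 22.7) and in an intron of Gata4 (20.7). Another, weaker peak lay 274 bp from the 5' end of Ctcf (17.4). Nkx2-5, a cardiac homeobox gene, had none within 10 kb, and the nearest was 20.2 kb away (28.5).

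**Figure D5:**
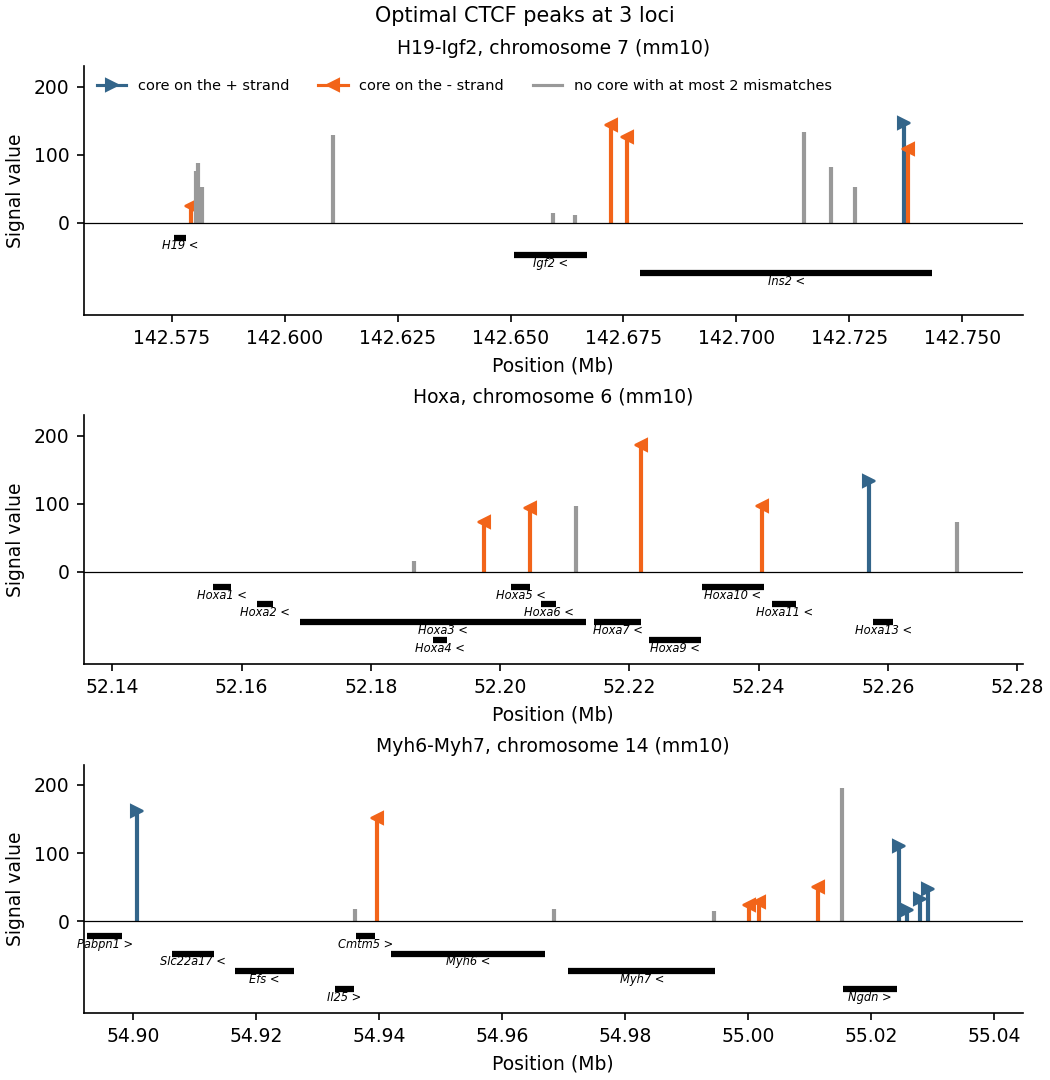
Optimal CTCF peaks at H19 and Igf2 (chromosome 7), Hoxa (chromosome 6) and Myh6 and Myh7 (chromosome 14), position in Mb (mm10) against the authors' signal value as line height, with arrowheads for the strand of the core and grey lines for peaks with no core of at most 2 mismatches. Black bars are H19 and protein-coding genes with their strand, without genes that have only a clone or model name, and the Hoxa7 promoter peak reaches 187.

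The X chromosome had fewer peaks per length than any autosome. It held 1137 optimal peaks, 6.95 per Mb of known sequence, against an autosome median of 18.4 and a range of 14.4 on chromosome 3 to 27.4 on chromosome 11. The ratio of X to the median autosome was 0.379, and 0.376 ± 0.00786 (SD, n = 2) in the replicates. Per protein-coding gene the ratio was 0.557. The median signal on X was 48.5, below the autosome range of 55.0 to 66.3. At Xist, the RNA gene that silences an X chromosome, the strongest site lay 989 bp upstream within Tsix, with a signal of 142. The Y chromosome held 1 optimal peak, and as the sex of the animals was not collected, the number of X copies per cell is unknown.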

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

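Both measurements here were chosen after the peak lists had been seen. Of the pooled relaxed peaks on the assembled chromosomes, 251957 lay more than 100 bp from any summit of the IDR lists and took no part in the comparisons. A core with at most 2 mismatches was present at 7.52% of them, above the 2.33% in windows 1000 bp to either side, which is what drew attention to them. The 10000 strongest of these peaks had a core at 36.9%, against 3.06% and 2.52% in the left and right windows, and the 50000 weakest at 3.8%, against 2.19% and 2.16%. No explanation was tested.

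A further 15 optimal peaks lay on sequences outside the assembled chromosomes, which no comparison of position used, with 9 of them on 1 unplaced sequence, where the highest signal was 157. No explanation was tested.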

How the results depend on the processing

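The narrow gap classes were chosen after the data were seen, the other alternatives before the data were examined. No paired analysis was possible because there is only 1 group. Of 119 alternatives on single gene lists, most of which did not pass at the start, 100 kept the result, and of the 59 others 31 did, while 22 moved in value, 2 no longer passed and 4 reversed. Promoter and core shares stayed above their controls in each of theirs, 7 for either share, which include either library used alone. The 2 lists passing in the conservative list were Hox and ion channel genes. The number of peaks was 22267 at or above the median signal. Replicate overlap was 85.8% for intervals sharing 1 bp, 77.7% for 50% of both lengths, 76.0% for summits within 25 bp, 88.8% for the top 10000 and 48.6% for the top 100000. The correlation was 0.927 as Pearson on log2 signal, 0.959 in the conservative list and 0.957 within 25 bp. All are over peaks that had passed the authors' IDR filter, which may raise the correlation. The log2 difference of peaks with a core was 1.28 in the conservative list, 1.55 with 3 mismatches and 1.33 to 1.47 in the other library's own strongest peaks with either replicate left out. That of promoters was -0.37 in the conservative list and -0.31 at the wider promoter window. The convergent share turned above the shuffled one at 50 to 500 kb (31.2%) and, in classes added after the data were seen, at 50 to 100 (28.7%), 100 to 200 (31.9%) and 200 to 500 kb (37.2%). It was below without passing at 25 to 50 kb (24.3%) and, over 5 to 200 kb, at or above the median signal (24.7%). The number of lists passing, 2, became 1 at 5 kb, 4 at 50 kb, 4 with a matched background, 0 with clustered members counted once (4 of 17 had an unadjusted Fisher's exact p under 0.05 there), and 4 to 6 with either replicate left out. Hox genes no longer passed at 5 kb (51.3%) or counted once (70%), nor imprinted genes in the conservative list (64.9%), at 5 kb (56.1%), at 50 kb (91.2%) or counted once (70.4%). Blood genes turned from below to above the rest at 50 kb (100%). The X ratio was 0.371 to 0.382 with either replicate left out and 0.557 per protein-coding gene. The cause was not tested. Read depth is not given, which leaves the noise of weak peaks unmeasured.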

Other observations

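The comparisons at identical GC content, with windows beside the summits and of masked cores without a B2 head were chosen after the result was seen, the other tests before, but the patterns were noticed in the same data, so each explanation is a hypothesis.

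Among genes of the heart and housekeeping lists, 48 had an optimal peak within 1000 bp of the 5' end, and at 25 of them the strongest such peak had no core with at most 2 mismatches. These included the transcription factor genes Gata6, Tbx20, Srf, Mef2d and Tbx18, the channel genes Kcnh2 and Kcnj2, and Lpl and Sdha. The sarcomere genes Myh7, Myom1 and Lmod2 were among them too. The peaks at Ryr2, Actn2, Tnni3, Tpm1, Kcnq1 and Ppara did have a core, as did those at the transcription factor genes Myocd, Tbx1 and Tbx3. Over all promoter peaks of the optimal list, counted per peak and not per gene, 2850 of 6298 had no core. The genes named were chosen after their values were seen.

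The most frequent core in masked repeats, CCAGAAGAGGGCAT, accounted for 1153 of 5930 masked cores (19.4%) with a median signal of 30.9, and CCAGAAGAGGGCAC for another 767 (12.9%), median signal 35.4. Outside repeats the most frequent, CCACCAGGGGGCAG, accounted for 231 of 26796 (0.862%) with a median signal of 148.

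Of the 11792 peaks without a core, 7912 had a match with 3 mismatches. Such matches outside masked sequence, where 1 was best, lay a median of 7.5 bp from the summit. In the left and right windows they lay 22.5 bp from the centre, so many peaks without a core may still hold a poorer CTCF site. Peaks without a core lay at promoters more often (24.2% of 11792) than peaks with one (10.5% of 32726). Weak peaks near the end of the list are argued against as the whole cause: within deciles of signal the difference stayed at 13.5 percentage points on average, and above 0 in 10 of 10 deciles. GC-rich sequence is argued against as the whole cause too, although it may carry part, since the difference was 7.675 percentage points on average within deciles of GC content, from 0.155 in the lowest to 15.1 in the highest, and 7.12 ± 0.414 (SD of 100 bootstraps) between peaks of identical GC content. Whether promoters in use in heart carry the pattern stays open: 25 of 48 such listed genes (52.1%) lacked a core against 1 of 6 neural, hepatic and blood genes (16.7%; Fisher's exact test, two-sided, p = 0.1938), too few to decide. No measurement of promoter activity was used here.

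Core orientation depended on the gap, with fewer convergent pairs than shuffled at 5 to 50 kb (21.3%) and more at 50 to 500 kb (31.2%). Cores in repeats are argued against as the cause of the short-gap deficit, which stayed at -13.27 shuffle SDs with masked cores left out. Weak peaks are argued against as the cause of the long-gap excess, which was 22.3 shuffle SDs among peaks at or above the median signal. Both tests used 1000 shuffles. No biological explanation was tested, and no contact map was used here.

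Cores in masked sequence lay in weaker peaks than other cores, with median signals of 36.6 and 92.4, a log2 difference of -1.34. Chance matches are argued against, since masked core centres lay a median of 6.5 bp from the summit, where the 333 and 348 masked cores with 1 best match in the left and right windows lay a median of 23.5 bp from the window's centre. Whether poorer matches are the cause stays open. At equal mismatch counts the difference was -1.08 on average. Equal counts need not mean equally good matches, since the 5 most frequent masked cores share a mismatch at the same base of the consensus. For cores with 0 mismatches the difference was -0.16, against -1.41 with 1 mismatch and -0.96 with 2. The comparison at equal counts therefore cannot decide whether poorer matches carry the pattern. Copies of the B2 repeat stay open. A head sequence was written from textbook knowledge, without a repeat annotation. It lay on the opposite strand within 250 bp of 17.93% of masked cores and 0.605% of others, short of the 50% set in advance. Masked cores without such a head still had a median signal of 39.7, against 92.7 for unmasked ones. The copies found at 75% identity therefore do not account for the pattern, while diverged or shortened ones would escape this search. Each of the 5 most frequent masked cores is 1 sequence repeated across peaks, and a head was found at 11.9% to 34.0% of these. A missing head therefore does not show that no copy is present, and the median of 39.7 cannot decide the question. Placement of reads in repeats and any biological explanation were not tested.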
